A study of Gnathonemus petersii with 18 samples.

How the data were processed

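RNA from the trigeminal ganglion, the cerebellum and the spinal cord of the elephantnose fish was sequenced, with 6 libraries per tissue, 18 in all; per the labels the tissues came from 6 individual fish. Total RNA was extracted with TRIzol, and libraries were made with a low-input kit that does not mark the strand. The strand setting used in counting, the genome build and the annotation are not given in the sources used here, so gene positions are not printed. The deposited table holds raw counts per gene and library, per the file headers, made by the authors with CASAVA 1.8.2, Trimmomatic 0.39, STAR 2.7.7a, featureCounts and Subread 2.0.1 according to the submitters' processing notes. The same deposited table holds TPM values, corrected for gene length and scaled by the authors within each library, per the file headers. Counts divided by TPM gave a single length per gene across libraries, with a largest relative SD of 5.3e-15.

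The table has 28031 genes, of which 17658 carry only a locus identifier and 10373 a symbol, and 1122 have no count in any library. Genes with a locus identifier took 52.8% of the counts. They were tested, but they could not join a list by symbol, so a list holds only those members that the annotation names. Reads shared between gene copies, or lost where copies are alike, were not examined. All columns of sample values were used.

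Replicates are libraries from different animals, and p-values describe differences between tissues against the spread between libraries. With total counts from 10346375 to 17587837 per library, counting error was small beside that spread for all but rare genes. A fold against a tissue with no count was computed against a floor of 3 counts over its 6 libraries and is written as a lower bound. With 1 to 3 counts, the ratio of summed, scaled counts is given with its 95% exact binomial (Clopper-Pearson) interval. Intervals and floors cover counting error only. No pair of libraries of a tissue was a copy of another: the lowest chi-square per degree of freedom between a pair was 13.6.

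Calculations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9 for figures. Genes were kept by filterByExpr of edgeR, which left 20691, scaled by TMM, and compared among the 3 tissues by the edgeR quasi-likelihood F-test fitted to all 18 libraries with 15 residual degrees of freedom. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Lists were tested by camera of limma with a preset correlation between genes of 0.01 and, as an alternative, with an estimated one. Its p-values were adjusted by Benjamini-Hochberg over 27 lists of at least 3 tested members and 3 comparisons. The levels of piezo2 and piezo1 within the ganglion were compared on log2(TPM + 0.1) by an exact two-sided sign-flip permutation test. Gene sets higher in a tissue than in both others were set beside simulated unchanged tissues and beside divided shared libraries.

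The lists, the tests, the thresholds and the rule for naming genes were fixed before the data were examined. Symbols were matched after conversion to capitals, duplicate suffixes of bony fish included. For each comparison the rule named the 5 highest and 5 lowest called genes with a symbol, an average log2 CPM of at least 5 and no overlap between the libraries of the tissues. From each list it named up to 3 called members with the largest absolute change and an average log2 CPM of at least 1 and, where most members were not called, the most abundant uncalled member. It also named a fixed set of receptor genes, among them PIEZO1, PIEZO2, TRPV1, TRPA1, TRPM8, NTRK2, NTRK3 and RET, and for each tissue the 10 genes with the greatest smaller-of-2 fold change against the other tissues. Some genes that the rule names are not reported here, and they stay in the counts of named genes.

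The labels number the libraries of each tissue from 1 to 6 without saying whether a number stands for a fish. After the tissue mean of each gene was removed, libraries with the same number correlated at 0.124 to 0.403 between ganglion and spinal cord and at 0.216 to 0.404 between spinal cord and cerebellum, all above 0.1, so the numbers were treated as pairing these tissues, and through the spinal cord also ganglion with cerebellum. Between those, same-number libraries correlated at 0.0759 to 0.297, above 0.1 in 4 of 6 pairs. The same number was the best match for 6 of 6 libraries from either side. Between ganglion and spinal cord it was the best match for 5 of 6 ganglion libraries and 6 of 6 spinal cord libraries. Between spinal cord and cerebellum it was for 6 of 6 from either side. The highest mean correlation with other numbers was -0.014. Removing the tissue mean by itself pushes these correlations below 0 where the same number correlates, so their sign adds no support. The pairing thus comes from the data. All these correlations are across genes, which are not independent replicates. The replicate number was therefore tried as a block, while the main fit leaves the pairing out.

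The procedure was tested on simulated counts for all 18 libraries, drawn from the mean of each gene over all 3 tissues and its spread. For each comparison 200 genes with an average log2 CPM above 1 were changed, in equal numbers up and down. That is far fewer than the genes called in the data, so the scaling was not tested under so large and uneven a change. For ganglion and cerebellum, 37 of 100 genes changed 2-fold and 92 of 100 changed 4-fold were called, with 5 false calls among 20472 genes. For ganglion and spinal cord these numbers were 35, 90 and 9 among 20498, and for spinal cord and cerebellum 31, 93 and 0 among 20493. A list with raised genes was called in each case, and 0 of 26 random lists were. Genes were drawn independently, so these random lists held no correlation between members. They cannot show how often camera calls a list of correlated genes by error.

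The alternatives tried were DESeq2 with its size factors, RLE size factors in edgeR, no filter on low counts, the replicate number as a block, only the libraries of the tissues compared, limma on log2(TPM + 1) for genes of at least 1 TPM in 6 libraries, an adjusted p under 0.01, an absolute log2 fold change of at least 2, an estimated correlation in camera, pseudocounts of 1 and 0.01 for the piezo genes, and leaving out each library. A pair of alternatives was added after the data were seen: leaving out ganglion replicates 2 and 5, and leaving out the 4 libraries highest in acta1.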

Results

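Gene expression was measured by RNA sequencing in the elephantnose fish (Gnathonemus petersii), a weakly electric freshwater fish. Libraries came from 3 tissues with 6 libraries each, 18 in all: the trigeminal ganglion, which holds the cell bodies of the neurons that carry touch, temperature and pain from the head; the cerebellum; and the spinal cord. The series title places the data in a study of how early fine touch arose among vertebrates. Total gene counts ran from 10413024 to 14183733 per ganglion library, from 10953416 to 17587837 per cerebellum library and from 10346375 to 13379441 per spinal cord library. Genes with at least 1 count numbered 21768 to 23955 in the ganglion, 22727 to 23422 in the cerebellum and 23381 to 23745 in the spinal cord. Levels below are CPM, the counts relative to the scaled library size, given as mean ± SD with n = 6 unless stated otherwise. Each log2 fold change is followed by an approximate SE, its absolute value divided by the square root of its quasi-likelihood F. This SE was not estimated separately and is least reliable for genes with almost no counts in a tissue. Each list of genes is followed by the adjusted p of camera, limma's test of a list against all other genes.

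The tissues separated completely along the leading principal components, which held 51.0% and 26.9% of the variance. Spearman correlations across genes, which are not independent replicates, ranged from 0.843 to 0.973 within the ganglion, 0.969 to 0.983 within the cerebellum and 0.946 to 0.973 within the spinal cord. Between tissues the mean correlation was 0.691 for ganglion and cerebellum, 0.786 for ganglion and spinal cord, and 0.779 for spinal cord and cerebellum. Ganglion replicate 5 stood apart from its group: its mean correlation with the other ganglion libraries was 0.872, against 0.923 to 0.938 for the rest, and its 50 most abundant genes took 32.2% of the counts, against 15.4% to 20.9%. Ganglion replicate 2 lay beside replicate 5 on these leading components, and between replicate 5 and the other ganglion libraries on the component with 6.81% of the variance.

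**Figure D1:**
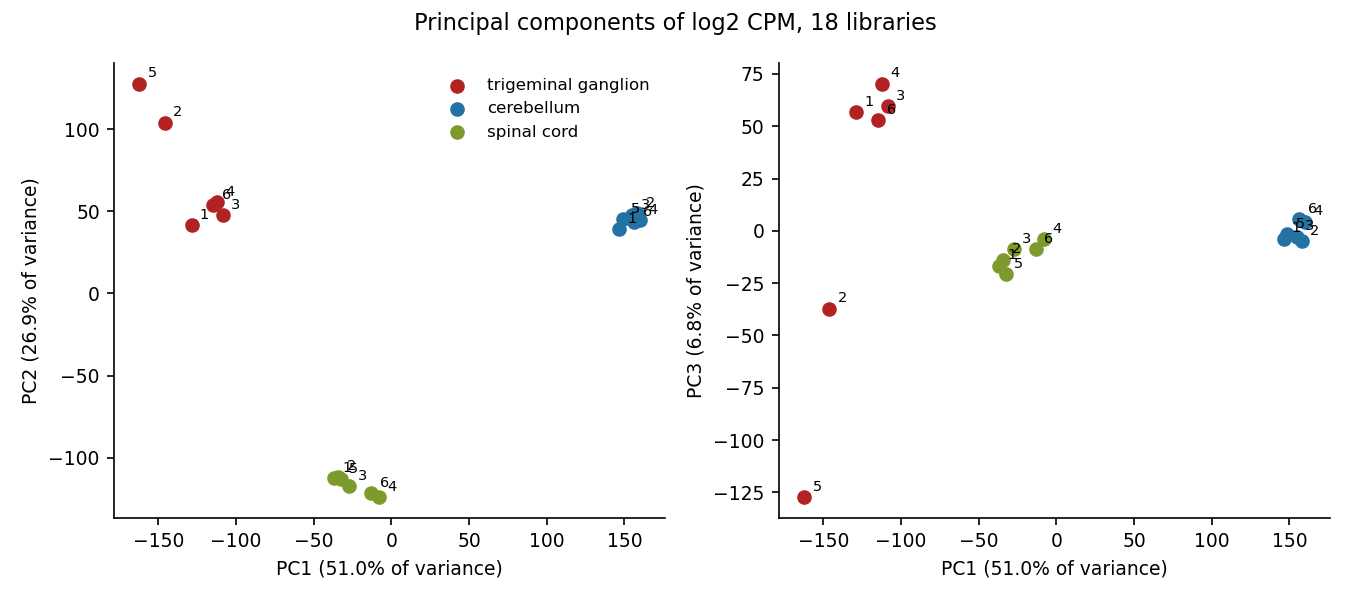
Principal components of log2 CPM for the 18 libraries, with replicate numbers beside the points and the share of variance in % on each axis. The 6 libraries of each tissue group together on the leading components (51.0% and 26.9%), and ganglion replicates 2 and 5 lie away from the other ganglion libraries, also on the component with 6.81%.

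The comparison of trigeminal ganglion with cerebellum asks what a sensory ganglion expresses beyond a central tissue. The ganglion carried the genes of sensory neurons and of their myelin. The homeodomain factors isl2 and isl1, which direct sensory and motor neuron identity, stood at 404.5 ± 62.5 and 251 ± 60.2 CPM in the ganglion without a single count in the cerebellum, so they were at least 12245-fold and at least 7183-fold higher against a floor of 3 counts over the 6 cerebellum libraries. Peripherin (prph), an intermediate filament of peripheral neurons, was higher by a log2 fold change of 11.87 ± 0.477, periaxin (prx), a protein of peripheral myelin, by 14.30 ± 1.15, and the tetraspanin gene tspan8 by 11.48 ± 0.579. In the other direction, the transcription factors pax8 (-10.68 ± 0.293), en2 (-10.24 ± 0.495) and pax2 (-9.41 ± 0.317), the vesicular GABA and glycine transporter slc32a1 (-9.77 ± 0.524) and the GABA-synthesising enzyme gad1 (-9.14 ± 0.569) were lower in the ganglion.

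Touch and pain receptor genes were tested singly and as lists. The mechanically activated channel gene piezo2, whose protein serves touch in vertebrates, was 10.1-fold higher in the ganglion (log2 fold change 3.34 ± 0.26, edgeR adjusted p = 1e-09, above the cerebellum mean in 6 of 6 libraries), and its relative piezo1 was 2.76-fold higher (1.47 ± 0.189, edgeR adjusted p = 1.09e-06); on the log2(TPM + 1) scale piezo1 reached 0.64 and was not called. Of 14 tested genes of the mechanically activated channel list, 5 were higher, 1 was lower and 8 were not called. Among them kcnk4 was at 3.19 ± 0.437, tmem120a at -3.17 ± 0.444 and tmem87a, uncalled, at -0.38 ± 0.124. The list did not stand out among all genes (camera adjusted p = 0.367). On the log2(TPM + 1) scale its median turned from 0.37 to -0.17, and of 13 members tested 2 were higher, 1 was lower and 10 were not called. Among 10 touch accessory genes, 3 were higher, 4 lower and 3 not called (camera adjusted p = 0.962, negative median and positive mean). The list member anxa6 was at 5.51 ± 0.26 and the vesicular glutamate transporter slc17a7 at -2.89 ± 0.345. Sensory ganglion identity genes were higher in 12 of 15 cases, lower in 1 and not called in 2 (camera adjusted p = 9.42e-08); ret, a receptor for GDNF-family ligands, was 163-fold higher (7.35 ± 0.451), and the BDNF receptor gene ntrk2 was at -0.45 ± 0.141 and not called. Of 5 nociceptor and thermoreceptor genes, 3 were higher, 1 lower and 1 not called (camera adjusted p = 0.0215, and adjusted p = 0.0619 with an estimated correlation). The irritant receptor gene trpa1 had 2858 counts in the ganglion and 1 in the cerebellum, a ratio of 3966 after scaling (95% counting interval 711 to 156700), and trpm2 and adcyap1 were higher by 5.51 ± 0.326 and 5.24 ± 0.324.

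Structural and glial genes followed. All 3 axonal intermediate filament genes were higher in the ganglion (camera adjusted p = 1.14e-05), among them nefl at 6.32 ± 0.482 and nefh at 4.28 ± 0.207. Peripheral myelin and Schwann cell genes were higher in 7 of 10 cases and not called in 3 (camera adjusted p = 1.42e-05). Of these, pmp22 was at 9.38 ± 0.539 and foxd3 at 9.81 ± 0.399; pmp22 reached 6912 CPM in ganglion replicate 5, against 1579 to 2746 in the other ganglion libraries. Oligodendrocyte genes split into 4 higher, 5 lower and 2 not called (camera adjusted p = 0.91). Within the list bcas1 was at 3.46 ± 0.186 and the lineage factor olig1 at -2.57 ± 0.343; on the log2(TPM + 1) scale 1 was higher and 5 were lower. Astroglia and radial glia genes were lower in 3 of 6 cases and not called in 3 (camera adjusted p = 0.0925), with the glutamate transporter gene slc1a3 at -4.34 ± 0.305 and the water channel gene aqp4 at -2.82 ± 0.349.

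Granule and unipolar brush cell genes were lower in the ganglion as a list, and Purkinje cell genes were not. Of 21 granule and unipolar brush cell genes, 16 were lower, 3 higher and 2 not called (camera adjusted p = 1.81e-09). The gene fat2 was at -9.02 ± 0.407 and pax6 at -6.79 ± 0.347. Purkinje cell genes were lower in 8 of 15 cases, higher in 5 and not called in 2 (camera adjusted p = 0.0631). The list member lhx1 was at -8.46 ± 0.599. Glycinergic and spinal interneuron genes were lower in 10 of 15 cases, higher in 4 and not called in 1 (camera adjusted p = 2.64e-07). AMPA, kainate, delta and NMDA receptor genes were lower in 7 of 11 cases and not called in 4 (camera adjusted p = 2.24e-06). Of these, grin2a was at -6.91 ± 0.264. GABA-A and glycine receptor genes were lower in 7 of 9 cases, higher in 1 and not called in 1 (camera adjusted p = 0.000848). Within the list gabrd was at -5.83 ± 0.372 and gabra6, typical of granule cells, at -5.35 ± 0.328. The motor neuron and cholinergic list had 8 of 15 members higher and 7 not called (camera adjusted p = 9.56e-05, and adjusted p = 0.0847 with an estimated correlation); its higher members isl1, isl2 and prph also belong to the sensory identity list, and the others were lhx3, ache, tbx3, uts2b and prima1, listed after their values were seen. Of these, uts2b had 5 ganglion counts against 0, at least 2.31-fold higher. Of the 15, 4 were higher on the log2(TPM + 1) scale.

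Ion channel families were mixed. Voltage-gated potassium channel genes were higher in 10 of 17 cases, lower in 1 and not called in 6 (camera adjusted p = 0.102). The gene kcnc4 was at 5.16 ± 0.223, while kcnd2 had 3 counts in the ganglion and 859 in the cerebellum, a scaled ratio of 206 (95% counting interval 70.4 to 1002). The sodium channel list held only the beta subunit genes scn2b, scn3b and scn4b. No gene of the pore-forming alpha subunits matched by symbol. Of the 3, scn4b was higher (3.45 ± 0.165), and the other 2 were not called (camera adjusted p = 0.0855). The list member scn3b was at 0.24 ± 0.388, a value that was -0.75 on the log2(TPM + 1) scale. TRP channel genes were higher in 4 of 9 cases and not called in 5 (camera adjusted p = 0.0914), and trpm7 was at -0.01 ± 0.156. ASIC and P2X channel genes were higher in 2 of 5 cases and not called in 3 (camera adjusted p = 0.251). Of these, p2rx7 was at 2.27 ± 0.183 and asic4 at 2.17 ± 0.283, and asic1 at 0.25 ± 0.204, which was -0.39 on the log2(TPM + 1) scale. On that scale 6 potassium channel genes were higher and 3 lower, and the median of the ASIC and P2X list was -0.15 in place of 0.49. Two-pore potassium channel genes gave 4 higher, 4 lower and 1 not called (camera adjusted p = 0.91). Within the list kcnk6 was at 2.58 ± 0.297 and kcnk12 at -2.57 ± 0.332. Of 8 tested on the log2(TPM + 1) scale, 2 were higher and 3 lower, with a median of -0.64 in place of -0.11, and 2 of 6 TRP channel genes were higher.

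Markers of other cell types were tested as lists, and none passed camera with both correlations. Fibroblast and connective tissue genes were higher in the ganglion in 10 of 11 cases and not called in 1 (camera adjusted p = 0.00135, and adjusted p = 0.282 with an estimated correlation). The gene col6a1 was at 6.81 ± 0.673 and postn at 7.71 ± 0.825. All 4 leukocyte genes were higher, among them cd74 at 2.55 ± 0.329, with a camera adjusted p of 0.173 that was 0.0489 with the replicate number as a block and 0.531 with an estimated correlation. Endothelial genes were higher in 3 of 8 cases, lower in 1 and not called in 4 (camera adjusted p = 0.313), and epithelium, cartilage and bone genes were higher in 3 of 4 and lower in 1 (camera adjusted p = 0.858). On the log2(TPM + 1) scale 2 leukocyte genes were higher, the filter left 7 endothelial genes, with 1 lower and 6 not called, and it left 2 of the 4 epithelium, cartilage and bone genes, with 1 lower and 1 not called. The erythrocyte list had 1 member, rhag, at 4.21 ± 0.504. Skeletal muscle genes were higher in 4 of 5 cases and not called in 1 (camera adjusted p = 0.313), and acta1, the actin of skeletal muscle, stood at 3252 CPM in ganglion replicate 1 and at 3.65 to 133 CPM in the other ganglion libraries. Immediate early and injury response genes gave 5 higher, 3 lower and 4 not called (camera adjusted p = 0.506). The list member gap43 was at 3.06 ± 0.174 and egr1 at -3.29 ± 0.336, and the list median of 0.41 was -0.17 on the log2(TPM + 1) scale. Hox genes were higher in 13 of 19 cases and not called in 6 (camera adjusted p = 0.167) at levels under 1 CPM in the ganglion, hoxd3 having 44 counts against 0, and these calls were lost on the log2(TPM + 1) scale. The added 1 shrinks changes at such low levels, so that loss decides little. Of 64 ribosomal protein genes 40 were higher and 24 not called (camera adjusted p = 1.61e-09, and adjusted p = 0.39 with an estimated correlation). Of these, rpl17 was at 1.67 ± 0.166, whereas on the log2(TPM + 1) scale 1 was called. Without ganglion replicates 2 and 5, left out after the data were seen, 38 ribosomal protein genes were higher, and 32 were without the 4 libraries highest in acta1 (ganglion replicate 1 and spinal cord replicates 1, 3 and 5), also left out after the data were seen.

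In all, 6132 of 20691 genes were higher in the ganglion and 4612 lower by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference. Each list count was the same when adjusted over the list alone. The higher genes made up 57.1% of the calls; with limma on log2(TPM + 1), where the median gene lay at -0.52 in place of 0.07, the same comparison gave 3075 higher and 7102 lower, or 30.2%. All 6 libraries of both tissues lay on the called side of the other tissue's mean for 67 of the 73 named and called genes, and at least 4 ganglion libraries did for the rest.

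The comparison of ganglion with spinal cord sets the sensory ganglion against a central tissue that also holds sensory relay and motor neurons. The ganglion was again higher in peripheral myelin and sensory identity genes, and lower in the genes that give the spinal cord its position along the body and its inhibitory neurons. Most motor neuron genes were lower as well, but as a list they did not pass camera with an estimated correlation. Among called genes with a symbol, an average log2 CPM of at least 5 and no overlap between libraries, those with the greatest excess in the ganglion were tspan8 (8.76 ± 0.5), rgs11 (8.25 ± 0.49), avil (7.63 ± 0.411), which codes for the actin-binding protein advillin of sensory neurons, prx (6.86 ± 0.799) and plekhd1 (6.65 ± 0.269). At the other end of this set stood hoxa9 (at least 3146-fold lower), hoxc8 (at least 2126-fold lower), hoxb8 (-12.17 ± 0.42), hoxb9, with 2 counts in the ganglion and 11865 in the spinal cord (scaled ratio 5275, 95% counting interval 1460 to 43564), and slc18a3, the vesicular acetylcholine transporter of motor neurons (-11.48 ± 0.596).

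Among receptor genes, piezo2 was 7.39-fold higher in the ganglion than in the spinal cord (log2 fold change 2.89 ± 0.255, edgeR adjusted p = 1.43e-08, above the spinal cord mean in 6 of 6 libraries), whereas piezo1 was at 0.36 ± 0.185 and not called, and at -0.02 on the log2(TPM + 1) scale. Mechanically activated channel genes gave 4 higher, 3 lower and 7 not called (camera adjusted p = 0.506). Within the list kcnk4 was at 2.51 ± 0.424 and tmc3 at -3.28 ± 0.536. Their median of 0.14 was -0.31 on the log2(TPM + 1) scale, where 2 were higher, 3 lower and 8 not called. Touch accessory genes gave 3 higher, 2 lower and 5 not called (camera adjusted p = 0.875, negative median and positive mean); slc17a7 had 568 counts in the ganglion and 3 in the spinal cord, a scaled ratio of 213 (95% counting interval 72.5 to 1036), and pcdh15, a gene of hair cell tip links, was at -4.90 ± 0.431. Sensory identity genes were higher in 9 of 15 cases, lower in 1 and not called in 5 (camera adjusted p = 4.16e-07). The gene isl2 was at 6.57 ± 0.215, isl1 at 5.92 ± 0.358 and ret at 2.08 ± 0.346, and with ntrk2 uncalled at -0.60 ± 0.141. Of the 5 nociceptor and thermoreceptor genes 4 were higher and 1, the substance P precursor tac1 (-7.05 ± 0.413), was lower (camera adjusted p = 0.181), and trpa1 was 19.6-fold higher (4.30 ± 0.311).

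Glial genes divided by myelin type. Peripheral myelin and Schwann cell genes were higher in 6 of 10 cases, lower in 1 and not called in 3 (camera adjusted p = 6.36e-05). The list member pmp22 was at 6.00 ± 0.463 and egr2, a factor of myelinating Schwann cells, at 4.37 ± 0.427. The myelin protein zero gene mpz, whose protein builds peripheral myelin and in fish also central myelin, was at 4827 ± 3378 CPM in the ganglion and 3546 ± 784 CPM in the spinal cord and was not called (0.45 ± 0.303, edgeR adjusted p = 0.232); it was chosen for this comparison after its values were seen. Oligodendrocyte genes were lower in 8 of 11 cases and not called in 3 (camera adjusted p = 1.39e-07). Of these, nkx2-2 was at -4.95 ± 0.326, olig1 at -4.36 ± 0.364 and olig2 at -3.67 ± 0.253. Astroglia and radial glia genes were lower in 5 of 6 cases and not called in 1 (camera adjusted p = 2.53e-05). Within the list slc1a3 was at -4.46 ± 0.307. Of the 3 axonal filament genes 2 were higher and nefl was not called (camera adjusted p = 0.0297, and adjusted p = 0.14 with an estimated correlation).

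Inhibitory neuron and receptor genes of the spinal cord were lower in the ganglion. Glycinergic and spinal interneuron genes were lower in 11 of 15 cases, higher in 2 and not called in 2 (camera adjusted p = 8.91e-19). The gene slc32a1 was at -9.02 ± 0.513, gad1 at -8.36 ± 0.557 and the glycine transporter gene slc6a5 at -8.29 ± 0.398. Motor neuron and cholinergic genes were lower in 10 of 15 cases, higher in 4 and not called in 1 (camera adjusted p = 0.0102, and adjusted p = 0.33 with an estimated correlation); mnx1, a motor neuron factor, was at least 451-fold lower and uts2b was at -11.03 ± 0.416, and the higher members were isl1, isl2, prph and tbx3. Granule and unipolar brush cell genes were lower in 12 of 21 cases, higher in 4 and not called in 5 (camera adjusted p = 0.000691, and adjusted p = 0.0518 with an estimated correlation), and Purkinje cell genes were lower in 6 of 15, higher in 4 and not called in 5 (camera adjusted p = 0.367). Glutamate receptor genes were lower in 9 of 11 cases, higher in 1 and not called in 1 (camera adjusted p = 1.28e-08). The list member grin2a was at -5.41 ± 0.257. GABA-A and glycine receptor genes were lower in 8 of 9 cases and higher in 1 (camera adjusted p = 2.5e-10). Of these, gabrg1 was at -7.04 ± 0.409. All 19 Hox genes were lower in the ganglion (camera adjusted p = 1.63e-58), hoxa7 by at least 1596-fold.

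Channel and background lists varied. All 3 sodium channel genes of the list, which are beta subunit genes, were higher (camera adjusted p = 0.0265, and adjusted p = 0.067 with an estimated correlation). Within the list scn4b was at 1.69 ± 0.154; 1 of the 3 was called on the log2(TPM + 1) scale. Potassium channel genes gave 7 higher, 6 lower and 4 not called (camera adjusted p = 0.331), TRP channel genes 2 higher, 3 lower and 4 not called (camera adjusted p = 0.877, with a positive test direction and a negative median and mean), and ASIC and P2X genes 1 higher and 4 not called (camera adjusted p = 0.42), the higher gene being asic4 (4.98 ± 0.329). Two-pore potassium channel genes gave 2 higher, 2 lower and 5 not called (camera adjusted p = 0.902). Fibroblast genes were higher in 7 of 11 cases, lower in 1 and not called in 3 (camera adjusted p = 0.0162, and adjusted p = 0.416 with an estimated correlation). The gene col6a1 was at 4.21 ± 0.586. The 4 leukocyte genes were not called (camera adjusted p = 0.89). Among them cd74 was at 0.48 ± 0.312, or -0.06 on the log2(TPM + 1) scale. Endothelial genes gave 1 higher, 3 lower and 4 not called (camera adjusted p = 0.218), epithelium, cartilage and bone genes 2 higher, 1 lower and 1 not called (camera adjusted p = 0.91). On the log2(TPM + 1) scale the filter left 7 endothelial genes, with 3 lower and 4 not called, and 2 epithelium, cartilage and bone genes, both not called. The erythrocyte gene rhag was higher (2.26 ± 0.462). Ribosomal protein genes were higher in 35 of 64 cases and not called in 29 (camera adjusted p = 3.8e-17, and adjusted p = 0.22 with an estimated correlation). The list member rps15 was at 1.53 ± 0.193, and on the log2(TPM + 1) scale 1 was higher and 1 lower.

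Some of these calls rested on few libraries. Of 5 skeletal muscle genes, tnnt1 was called higher and 4 were not called (camera adjusted p = 0.91); tnnt1 stood at 147 CPM in ganglion replicate 1 and at 7.90 to 14.1 in the other ganglion libraries, and its log2 fold change of 2.16 became 1.24 with the replicate number as a block (edgeR adjusted p = 0.0898). Immediate early and injury genes were higher in 5 of 12 cases and not called in 7 (camera adjusted p = 0.209). Of these, atf3 was at 2.39 ± 0.333 and fosl2 at 2.26 ± 0.625. The list had 3 higher and 2 lower on the log2(TPM + 1) scale, and of 6 muscle genes tested there 2 were lower and 4 not called. Without ganglion replicates 2 and 5, 3 immediate early and injury genes were higher and 1 was lower. The values of fosl2 and kcnk6 were then 0.87 and 0.60, neither called, mb was called at -1.37, and 3 in place of 4 nociceptor genes were higher. Without ganglion replicate 1 and spinal cord replicates 1, 3 and 5, the libraries highest in acta1, tnnt1 was at 0.44 and col10a1, krt18 and scn3b were no longer called, which left 2 sodium channel genes higher, 3 immediate early and injury genes higher and the epithelium, cartilage and bone genes uncalled. Both sets of libraries were left out after the data were seen.

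In all, 2990 genes were higher in the ganglion and 3579 lower by the same edgeR test. Adjusted over the list alone, the counts were the same except that 2 epithelium, cartilage and bone genes in place of 1 were lower. The higher genes made up 45.5% of the calls; limma on log2(TPM + 1), with the median gene at -0.37 in place of -0.01, gave 1201 higher and 4336 lower, or 21.7%. All 6 libraries of both tissues lay on the called side for 70 of 75 named and called genes.

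**Figure D2:**
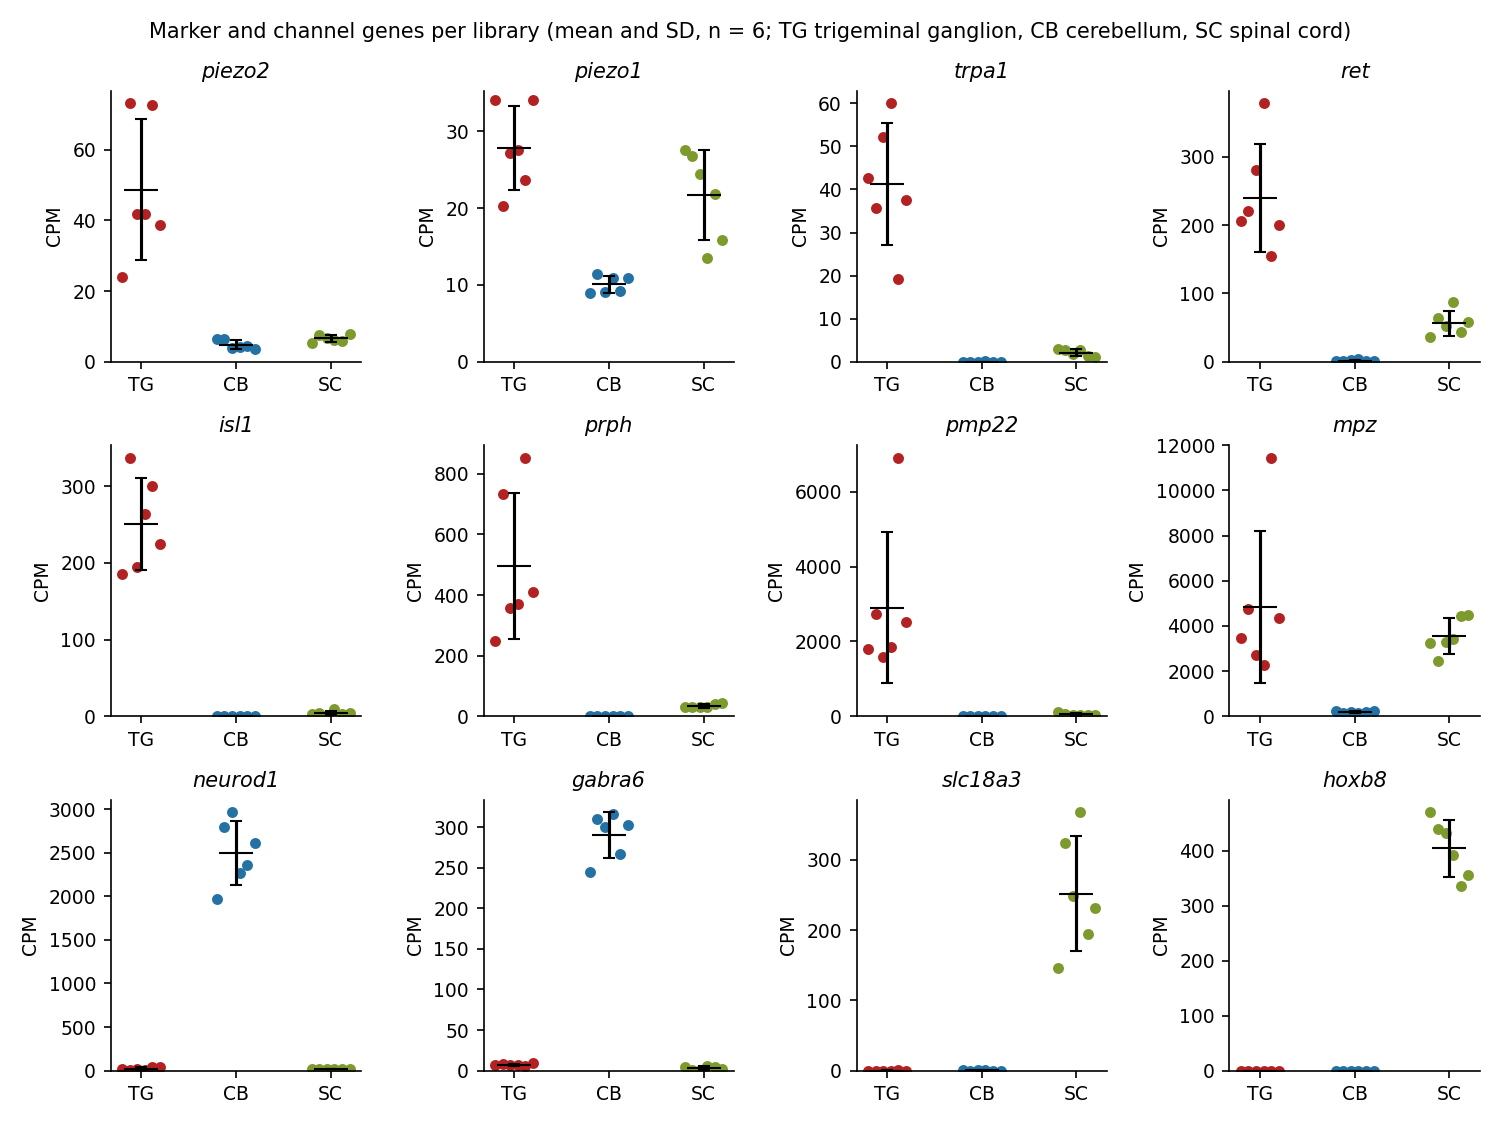
CPM of 12 genes in each library (points), with the mean and SD of the 6 libraries (lines), in the trigeminal ganglion (TG), cerebellum (CB) and spinal cord (SC). The axis of each panel starts at 0. Levels of piezo2, trpa1, isl1, prph and pmp22 are highest in the ganglion, neurod1 and gabra6 in the cerebellum, and slc18a3 and hoxb8 in the spinal cord, while mpz is high in both ganglion and spinal cord.

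The comparison of spinal cord with cerebellum contrasts 2 central tissues. The spinal cord was higher in Hox genes, motor neuron genes and oligodendrocyte genes, and the cerebellum in genes of its granule cells. The neuropeptide gene uts2b was at least 5529-fold higher in the spinal cord, and hoxb9, hoxd3, hoxa9 and hoxb6 were at least 4880-fold, 4570-fold, 4366-fold and 4217-fold higher, each without a count in the cerebellum. The cerebellum was higher in en2 (-13.65 ± 0.596), the cadherin gene fat2 (-11.42 ± 0.481), neurod1, a factor of granule cell differentiation (-7.10 ± 0.47), gabra6 (-6.48 ± 0.348) and zbtb18 (-6.39 ± 0.344).

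Neuronal lists differed as follows. Motor neuron and cholinergic genes were higher in the spinal cord in 14 of 15 cases and not called in 1 (camera adjusted p = 5.05e-16), and lhx4 was at least 344-fold higher. All 19 Hox genes were higher (camera adjusted p = 4.48e-51). Granule and unipolar brush cell genes were lower in 10 of 21 cases, higher in 5 and not called in 6 (camera adjusted p = 0.000147), and slc17a7 had 6766 counts in the cerebellum and 3 in the spinal cord (scaled ratio 1828, 95% counting interval 625 to 8865). Purkinje cell genes gave 4 higher, 5 lower and 6 not called (camera adjusted p = 0.118). Within the list ptf1a was at -6.52 ± 0.323. Glycinergic and spinal interneuron genes gave 5 higher, 2 lower and 8 not called (camera adjusted p = 0.367, negative median and positive mean). The gene slc6a5 was at 5.64 ± 0.33. GABA-A and glycine receptor genes gave 4 higher, 3 lower and 2 not called (camera adjusted p = 0.177, negative median and positive mean). The list member glra1 was at 6.05 ± 0.175, and glutamate receptor genes gave 2 higher, 3 lower and 6 not called (camera adjusted p = 0.367). In limma on log2(TPM + 1), 4 glutamate receptor genes were lower and 7 not called, and 2 of 14 Purkinje cell genes were higher and 5 lower.

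Several genes of the sensory lists were higher in the spinal cord than in the cerebellum. Of these, isl1, isl2 and prph also belong to the motor neuron and cholinergic list, of which 14 of 15 members were higher. Sensory identity genes were higher in 9 of 15 cases, lower in 2 and not called in 4 (camera adjusted p = 0.00822): drgx, a factor of sensory ganglia and dorsal horn neurons, had 2392 counts against 3 (scaled ratio 984, 95% counting interval 336 to 4774), and ret was 38.4-fold higher (5.26 ± 0.416). Of 5 nociceptor and thermoreceptor genes 4 were higher and 1 lower (camera adjusted p = 0.0215, and adjusted p = 0.0619 with an estimated correlation), and trpa1 had 154 counts against 1 (ratio 190, 95% counting interval 33.6 to 7554). On the log2(TPM + 1) scale trpa1 reached 0.93 and piezo1 0.67, and neither was called. The added 1 shrinks the change of a gene at low TPM, so these lost calls alone decide little. Mechanically activated channel genes gave 4 higher, 3 lower and 7 not called (camera adjusted p = 0.786). Of these, piezo1 was at 1.10 ± 0.188 and piezo2 uncalled at 0.45 ± 0.247; piezo1 was at 0.90 and no longer called without the 4 libraries highest in acta1. Touch accessory genes gave 4 higher, 1 lower and 5 not called (camera adjusted p = 0.91, positive median and negative mean). Within the list anxa6 was at 3.81 ± 0.241, and their median of 0.21 was -0.26 on the log2(TPM + 1) scale. The BDNF receptor gene ntrk2 was at 0.15 ± 0.141, or -0.08 on that scale. All 3 axonal filament genes were higher (camera adjusted p = 7.84e-05). The gene nefl was at 6.22 ± 0.48. TRP channel genes were higher in 5 of 9 cases and not called in 4 (camera adjusted p = 0.0381, and adjusted p = 0.114 with an estimated correlation). The list member trpc7 was at 5.87 ± 0.74.

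Among glial and other cell type lists, the oligodendrocyte list passed camera with both correlations. Oligodendrocyte genes were higher in 9 of 11 cases and not called in 2 (camera adjusted p = 9.34e-07), with fa2h, an enzyme of myelin lipid synthesis, at 4.32 ± 0.424, bcas1 at 3.93 ± 0.19 and myrf at 3.41 ± 0.269. Peripheral myelin and Schwann cell genes were higher in 6 of 10 cases, lower in 1 and not called in 3 (camera adjusted p = 0.0309, and adjusted p = 0.127 with an estimated correlation). Of these, mpz was at 4.34 ± 0.347. Astroglia and radial glia genes gave 3 higher, 1 lower and 2 not called (camera adjusted p = 0.238). With DESeq2 this list gave 2 higher, 2 lower and 2 not called. Within the list hepacam was at 2.77 ± 0.192 and aqp4 at -2.26 ± 0.337. Endothelial genes were higher in 5 of 8 cases and not called in 3 (camera adjusted p = 0.0179, and adjusted p = 0.359 with an estimated correlation). The gene sox7 was at 2.22 ± 0.206. All 4 leukocyte genes were higher, with a camera adjusted p of 0.17 that was 0.0419 with the replicate number as a block and 0.531 with an estimated correlation, and 3 were higher without the 4 libraries highest in acta1. Fibroblast genes were higher in 8 of 11 cases and not called in 3, with a camera adjusted p of 0.0631 that was 0.0478 with the block and 0.531 with an estimated correlation; without the 4 libraries highest in acta1, 6 were higher. Skeletal muscle genes were higher in 4 of 5 cases and not called in 1 (camera adjusted p = 0.251), and in 2 without those libraries, when actn3 stood at 0.52 and was not called; acta1 was at 1295, 1119 and 1172 CPM in spinal cord replicates 1, 3 and 5 and at 106 to 295 CPM in the others. The erythrocyte gene rhag was higher (1.95 ± 0.462).

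Remaining lists showed little common direction. Sodium channel subunit genes gave 1 higher, 1 lower and 1 not called (camera adjusted p = 0.867), potassium channel genes 8 higher, 3 lower and 6 not called (camera adjusted p = 0.344), ASIC and P2X genes 2 higher, 1 lower and 2 not called (camera adjusted p = 0.781) and two-pore potassium channel genes 3 higher, 2 lower and 4 not called (camera adjusted p = 0.987). With limma on log2(TPM + 1), 4 of 15 potassium channel genes were higher and 2 lower, and 2 of 8 two-pore genes were higher and 2 lower. There 1 ASIC or P2X gene was higher and 1 lower, with a median of -0.13 in place of 0.07. Immediate early genes gave 4 higher, 5 lower and 3 not called (camera adjusted p = 0.89), and epithelium, cartilage and bone genes 1 higher, 1 lower and 2 not called (camera adjusted p = 0.91). Of 64 ribosomal protein genes 2 were higher and 62 not called (camera adjusted p = 0.962, with a negative test direction, and a positive median and mean that turned to a median of -0.15 on the log2(TPM + 1) scale). The list member rpl7a was at -0.17 ± 0.156.

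By the edgeR test 5980 genes were higher in the spinal cord and 3369 lower. Adjusted over the list alone, 2 astroglia genes in place of 1 were lower and 5 Purkinje cell genes in place of 4 were higher, and the other lists kept their counts. The higher genes made up 63.96% of the calls; limma on log2(TPM + 1), with the median gene at -0.14 in place of 0.08, gave 4014 higher and 3872 lower, or 50.9%. All 6 libraries of both tissues lay on the called side for 78 of 79 named and called genes.

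**Figure D3:**
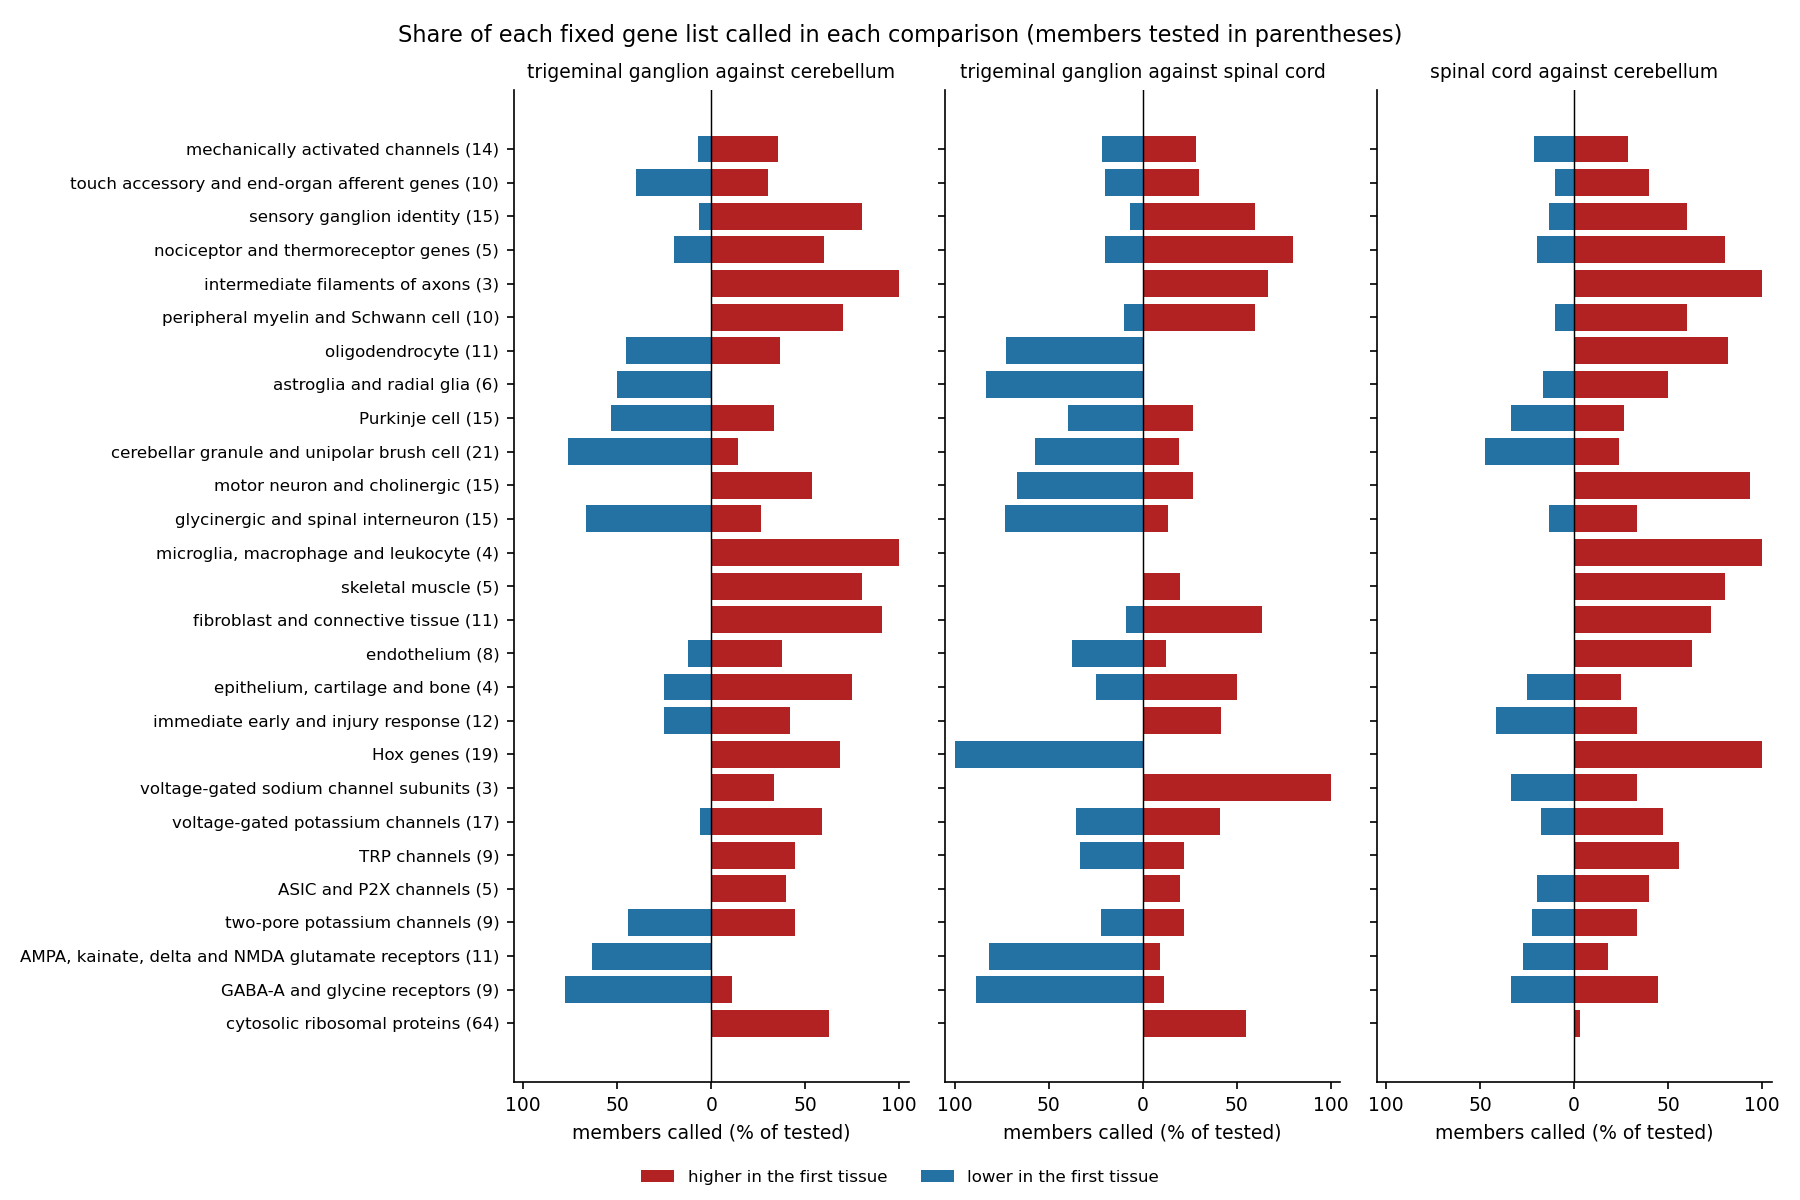
Share of the tested members of each gene list, in %, that were called higher (red, to the right) or lower (blue, to the left) in the tissue named first, for the 3 comparisons, with the number tested in parentheses; the erythrocyte list with 1 member is not drawn. All 19 Hox genes were higher in the spinal cord than in either other tissue, and the 40 of 64 ribosomal protein genes higher in the ganglion than in the cerebellum fell to 1 on the log2(TPM + 1) scale.

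Genes higher in a tissue than in both others numbered 2190 for the ganglion, 2398 for the cerebellum and 1681 for the spinal cord. In the ganglion the 10 symbols with the greatest smaller-of-2 fold change were rgs11, tspan8, prx, depdc7, plekhd1, pmp22, isl1, isl2, tpd52l1 and gng13; the G protein subunit gene gng13, for example, stood at 828 ± 382 CPM against 16.8 ± 4.43 in the cerebellum and 9.87 ± 2.14 in the spinal cord. In the cerebellum they included fat2, en2, neurod1, zbtb18, zic5, rpp25, zic2, gabra6 and raly, with zic2, a zinc finger factor of granule cell precursors, at 5535 ± 1330 CPM against 132 ± 29.2 in the ganglion and 116 ± 36.4 in the spinal cord. In the spinal cord they were uts2b, slc18a3, nppc and the Hox genes hoxa9, hoxb3, hoxb6, hoxb8, hoxb9, hoxc8 and hoxd3, with hoxb8 at 404 ± 52.0 CPM. Each such count joins 2 comparisons that share 6 libraries. Independent lists of the same lengths would share 886, 751 and 1034 genes, 20 simulated sets of unchanged tissues gave 0 genes each time, and with the shared libraries divided into groups of 3, in 10 ways, the counts ran from 1561 to 1983, from 2234 to 2327 and from 1358 to 1384. Unchanged tissues leave almost no calls to share, and independent lists have no libraries in common, so neither shows what shared libraries add. Only the divided libraries bear on that, with fewer libraries in each fit. By limma on log2(TPM + 1), 893 genes were higher in the ganglion than in both others.

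Within the ganglion, TPM values allowed genes to be compared with each other. All lists ranked here hold only genes with a symbol, so other family members may be missing from them. Whether each gene of the mechanically activated channel list codes for such a channel was not examined. In the mechanically activated channel list tmem150c was the most abundant at 41.5 ± 2.24 TPM (SD, n = 6). After it came tmem87a at 25.4 ± 2.49, pkd2 at 20.8 ± 7.77, tmc6 at 12.8 ± 8.11, tmc7 at 9.97 ± 4.29 and tmem63c at 8.43 ± 3.08. The piezo genes came next, piezo2 at 6.73 ± 1.77 and piezo1 at 4.85 ± 1.67 TPM. The piezo2 level exceeded that of piezo1 in 4 of 6 libraries, with a mean log2 ratio of 0.50 ± 0.87 (SD, n = 6), and the difference was not larger than the spread between libraries (exact two-sided sign-flip permutation test, p = 0.25, where 6 libraries allow a smallest p of 0.03125). The excess lay in ganglion replicates 2 and 5: without them, a choice made after the data were seen, the mean log2 ratio was 0.01 ± 0.52 (SD, n = 4), with piezo2 higher in 2 of 4 libraries (exact permutation p = 1, smallest possible 0.125). Among TRP channel genes trpm2 (22.0 ± 7.31) and trpa1 (14.9 ± 6.79) were the most abundant, and among ASIC and P2X genes p2rx7 (40.2 ± 13.6) and asic4 (27.9 ± 7.66). Of the growth factor receptor genes, ret was at 64.6 ± 28.3 TPM and ntrk2 at 19.8 ± 3.34. No symbol in the table matched NTRK3, TRPV1 or TRPM8, so these were not analysed here.

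**Figure D4:**
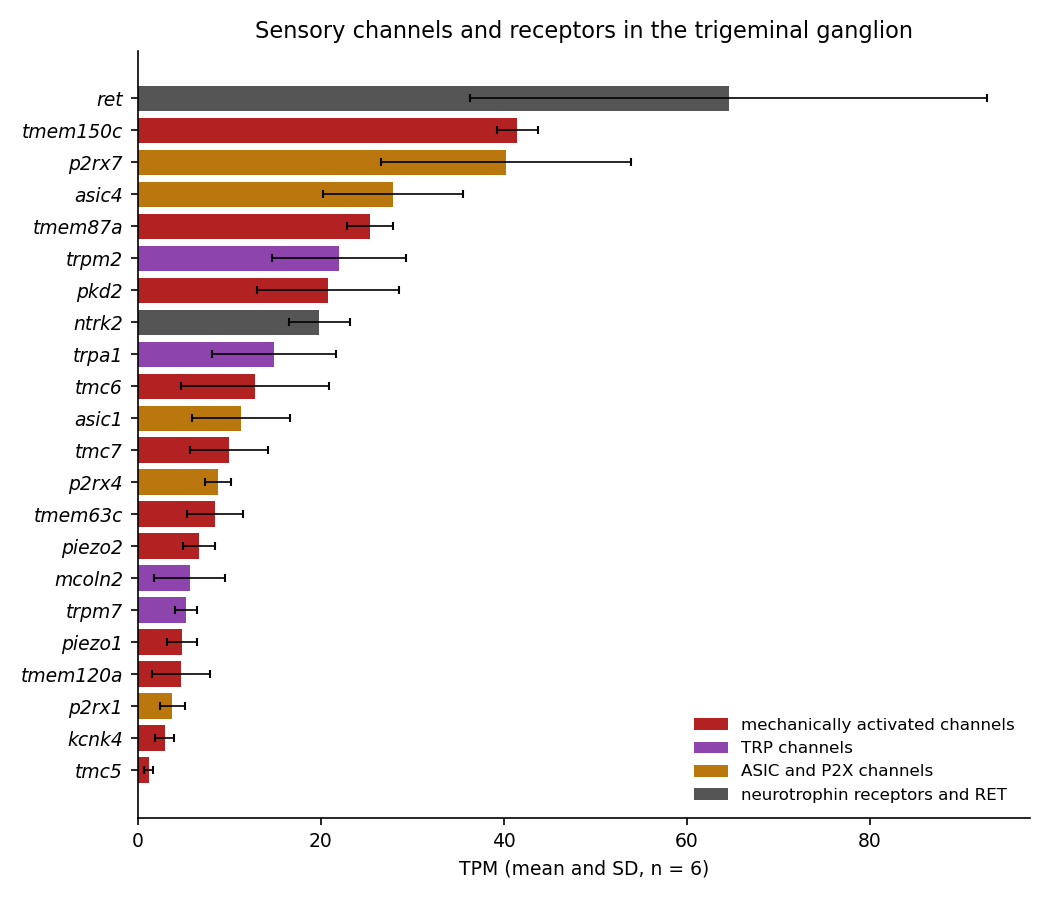
Mean TPM of channel and receptor genes in the trigeminal ganglion, with the SD of 6 libraries as error bars, coloured by family. The gene ret (64.6) and tmem150c (41.5), from the mechanically activated channel list, are the most abundant. The error bars of piezo2 (6.73) and piezo1 (4.85) overlap.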

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

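The tests of gene length and of a few abundant genes in ganglion replicate 5, of mpz and drgx in the spinal cord, and of other splits of the libraries were chosen only after the result was seen. In each of 392 groups of 6 libraries, the gap between an extreme library and its nearest neighbour was divided by the range of the group. Gene levels entered on a log2 scale after adding 1, and library measures entered unchanged. The gene levels printed below are CPM, so the gaps do not follow from them directly. Values above 0.625 before rounding stood out in 14 groups. Chance alone gives about 1 group in 20, so the 14 of 392 are no more than chance gives.

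In the ganglion, replicate 5 was highest in the share of its 50 most abundant genes, 32.2% against 15.4% to 20.9% (gap 0.67), and in pmp22, 6912 CPM against 1579 to 2746 (gap 0.625). Replicate 1 was highest in tnnt1, 147 CPM against 7.90 to 14.1 (gap 0.812), and in actn3, 181 CPM against 29.6 to 53.4 (gap 0.678), and lowest in asic4, 43.8 CPM against 83.9 to 103 (gap 0.755). Replicate 4 was lowest in zic5, 9.58 CPM against 18.9 to 23.6 (gap 0.749). In the cerebellum, replicate 5 was lowest in ntrk2, 111 CPM against 127 to 136 (gap 0.671), and replicate 2 was highest in kcnk1, 347 CPM against 227 to 258 (gap 0.693).

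In the spinal cord, replicate 1 was lowest in nefh, 613 CPM against 965 to 1166 (gap 0.705), in mnx1, 6.59 CPM against 17.9 to 31.5 (gap 0.626), and in lhx4, 5.67 CPM against 11.3 to 14.4 (gap 0.729), and highest in bcas1, 573 CPM against 495 to 515 (gap 0.726). Replicate 2 was lowest in grin2a, 12.5 CPM against 16.2 to 18.6 (gap 0.646). Replicate 4 was highest in nkx2-2, 33.1 CPM against 25.4 to 27.9 (gap 0.654).

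Ganglion replicate 5 differed more than 4-fold from the ganglion mean in 2512 genes, against 186 to 609 in the other ganglion libraries. A different mix of cell types alone was predicted to leave 32 proteasome subunits in step, if every cell makes them in a fixed ratio. Their log2 deviations in replicate 5 had an SD of 1.28, against 0.3898 to 0.542 in the other ganglion libraries. If that assumption holds, this argues against a cell mix as the only cause, and a cell mix beside another cause stays open. Gene length bias was argued against by a rank correlation across genes of -0.0297 between deviation and length, inside the range of the other libraries (-0.150 to 0.172), and a few genes taking most of the counts by a median absolute deviation of 1.145 without the 50 most abundant genes, against 0.499 to 0.680. The quality of the RNA or of the library, and a biological difference of this fish, stay open, and GC content was not tested for want of sequence. No biological explanation other than the cell mix was tested, since the groups give none for a single library.

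Skeletal muscle transcripts were high in ganglion replicate 1, where acta1 stood at 3252 CPM against 3.65 to 133. Muscle carried over with the ganglion is a candidate explanation: of 34 further muscle genes, 82.4% were highest in replicate 1, where chance gives 1 in 6. Reads shared among actin genes were argued against, since these further genes, none an actin, had a median log2 deviation of 1.86 in that library. No biological explanation was tested.

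In the spinal cord, mpz reached 73.5% and drgx 54.9% of the ganglion level. Nerve root or ganglion carried over with the spinal cord would bring other ganglion transcripts as well, but pmp22 reached 1.56%, prx 0.861% and egr2 4.82% of the ganglion level. At the greatest share that ganglion markers allow, carried-over ganglion would give 6.56% of the spinal cord level of mpz and 8.78% of that of drgx. A difference between tissues in which cells make these transcripts stays open as an untested hypothesis.

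Other splits of the 12 libraries of each comparison, 100 of the 462 possible with the real one included, were tested. The edgeR model was fitted to those 12 libraries alone, so its counts differ from those of the fit to all 18. Between ganglion and cerebellum the tissues gave 9907 calls and the highest other split 395, between ganglion and spinal cord 6122 and 0, and between spinal cord and cerebellum 8948 and 0, so 1 of 100 splits, the real one, gave as many calls each time. Since the numbers pair the libraries, the others include all 31 that part the 6 pairs as the tissues do, with highest counts of 395, 0 and 0, while the rest keep some pairs together. Each other split puts libraries of both tissues into both groups, so the difference between tissues widens the spread and few calls follow. The splits therefore cannot exclude chance beyond 1 of 100, nor a batch or a dissection that went with the tissue.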

How the results depend on the processing

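The settings without ganglion replicates 2 and 5 and without the 4 libraries highest in acta1 were chosen only after the data were seen, and the other tests were planned.

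For the named genes, 1416 of 1454 alternatives kept the direction and the call, 27 became weaker, 2 stronger and 9 reversed. DESeq2, RLE size factors, no filter on low counts, the block and only the tissues compared kept every count of genes within 1.5 times its value, as did an adjusted p under 0.01, and a gene called in opposite directions occurred in none of the scalings, TPM included.

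Limma on log2(TPM + 1) does not correct for composition and tests other genes, and its added 1 shrinks changes at low TPM. With it, 3075 genes were higher in the ganglion than in the cerebellum and 7102 lower, 1201 were higher than in the spinal cord, and 893 were higher than in both. With a log2 fold change of at least 2, which by construction leaves fewer genes, the number of genes higher in trigeminal ganglion than cerebellum was 3551 and of genes lower in trigeminal ganglion than cerebellum 2072. There were 980 genes higher in trigeminal ganglion than spinal cord and 1727 genes lower in trigeminal ganglion than spinal cord. There were 3209 genes higher in spinal cord than cerebellum and 1087 genes lower in spinal cord than cerebellum. Then 769 were genes higher in trigeminal ganglion than in both other tissues, 793 genes higher in cerebellum than in both other tissues and 753 genes higher in spinal cord than in both other tissues. With an estimated correlation in camera 21 lists and comparisons passed in place of 35.

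Reversed values were all uncalled. On the log2(TPM + 1) scale they were the log2 fold change of scn3b, trigeminal ganglion minus cerebellum (-0.75), the log2 fold change of asic1, trigeminal ganglion minus cerebellum (-0.39), the log2 fold change of cd74, trigeminal ganglion minus spinal cord (-0.057), the log2 fold change of asic1, trigeminal ganglion minus spinal cord (-0.19), the log2 fold change of kcnk1, trigeminal ganglion minus spinal cord (-0.40), the log2 fold change of piezo1, trigeminal ganglion minus spinal cord (-0.024) and the log2 fold change of ntrk2, spinal cord minus cerebellum (-0.076). With the replicate block the log2 fold change of scn3b, trigeminal ganglion minus cerebellum, was -0.008, and with only the 2 tissues compared the log2 fold change of trpm7, trigeminal ganglion minus cerebellum, was 0.013. The cause was not tested.

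With the block, 38 lists and comparisons passed, 35 of them shared with the main setting; the others were the leukocyte list for ganglion and cerebellum (adjusted p = 0.0489) and the leukocyte and fibroblast lists for spinal cord and cerebellum (adjusted p = 0.0419 and 0.0478). Among named genes the block ended the call of tnnt1 between ganglion and spinal cord (1.24), and it changed no other call.

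Leaving out each library in turn gave 6074 to 6283 genes higher and 4523 to 4766 lower in ganglion than cerebellum, 2586 (without ganglion replicate 5) to 3378 (without ganglion replicate 3) higher and 3442 to 3843 lower than in spinal cord, and 5849 to 6161 higher and 3328 to 3555 lower in spinal cord than cerebellum. Genes higher than in both others ran from 1896 to 2415 for the ganglion, 2359 to 2522 for the cerebellum and 1620 to 1838 for the spinal cord. The log2 ratio of piezo2 to piezo1 ran from 0.28 to 0.74, and was 0.42 and 0.51 with pseudocounts of 1 and 0.01 (exact permutation p = 0.25 for both). For PIEZO2 against PIEZO1 within the trigeminal ganglion it was 0.01 without ganglion replicates 2 and 5.

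Without ganglion replicates 2 and 5, 241 of 244 named values kept their call, and 1 changed its sign. The counts were then 2283 genes higher in trigeminal ganglion than spinal cord and 3418 genes lower in trigeminal ganglion than spinal cord. Without the 4 libraries highest in acta1, 237 values kept their call, and these counts were 2945 and 3589. In simulated data 90 to 93 of 100 changes of 4-fold were called; changes of exactly 2-fold lie at the threshold itself, so their lower number says nothing about depth.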

Other observations

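These values were chosen only after they were seen, and no test was run on them. Hox genes of the ganglion had their highest level relative to the spinal cord in hoxa2, with 58 counts against 281, or 22.2% of the spinal cord level, followed by hoxb2 with 3.23% and hoxa3 with 2.69%. In contrast hoxd3 reached 0.435% and hoxb8 0.0203%, and hoxa7, hoxc8, hoxa9 and hoxd10 had no counts in the ganglion, where a floor of 3 counts over the 6 libraries applies.

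The antiviral gene rsad2 stood at 613 CPM in ganglion replicate 2 and at 433 CPM in ganglion replicate 5, against 9.50 to 33.8 CPM in the other ganglion libraries. In the cerebellum it was at 20.9 CPM in replicate 5 and at 0.563 to 3.71 CPM elsewhere, and in the spinal cord at 36.8 CPM in replicate 5 and at 1.72 to 15.3 CPM elsewhere.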
